A study of Mus musculus with 10 samples.

How the data were processed

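Primary vascular smooth muscle cells were cultured from the aortic media of 8-week-old male mice and used between passages 2 and 7, per the labels' protocols. The passage of each library is not given in the sources used here, so it may differ between and within genotypes. The labels give 10 libraries: RNA from 3 wild-type and 3 Adamts7 overexpression mice, and ATAC-seq of 50000 cells from 2 mice of each genotype. All carry the same batch label, so batches could not be compared or corrected for. Groups were taken from the genotype label, and replicates from the mouse number in the title.

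The authors deposited 1 table of TPM (transcript abundance, corrected for length and scaled to one library total) per gene and library, named as kallisto output per the labels. Each column sums to 1000000. The build is mm10 per the submitters' processing notes; the kallisto version, the transcript annotation, the summing of transcripts to genes, trimming and read number are not given in the sources used here. TPM from kallisto are estimates in which reads shared by similar transcripts are divided between them, so near-identical gene copies are uncertain. TPM are relative, so abundant genes that differ lower the value of all others, and read number cannot be recovered from them.

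For ATAC-seq the authors deposited 1 table of footprint scores in the layout of TOBIAS BINDetect, per the file headers. It holds, for each motif, a mean footprint score per genotype, the number of sites searched and called bound, and a change score of wild type over overexpression with the authors' p-value. The authors' deposited p-value has 1 value per motif over pooled libraries and was quoted as theirs. The 2 mice of each genotype were merged in the deposited scores, so no SD, n or test of its own was given. Peak calling, the correction for transposase insertion, the threshold for a bound site and the scaling between genotypes are not given in the sources used here. The sign of the change was turned so that positive means higher in overexpression; it has a correlation of 0.994 with the log2 ratio of the mean scores, and its sign differs from the difference of mean scores for 48 motifs. It has a Spearman correlation of -0.65 with the wild-type score, so families were compared with random motif lists matched on mean score.

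Genes were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), in genes with a mean of at least 1 TPM over the 6 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2(TPM + 1) scale, which understates changes of low genes. Adamts7 was also tested with an exact permutation test. Gene lists were tested with camera of limma, with a preset correlation of 0.01, in the 21 of 27 lists with at least 5 tested members, adjusted over lists, and with camera with an estimated correlation, camera on ranks and fry. fry asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The lists covered contractile, lipid uptake, cholesterol efflux, sterol synthesis, fatty acid synthesis, chondrocyte-like, matrix, protease, AP-1, NF-kB, interferon, proliferation, senescence, unfolded protein response, TGF-beta and YAP, and hypoxia genes, markers of macrophages, endothelium, fibroblasts, Schwann cells, adipocytes, epithelium, striated muscle and erythroid cells, Y-linked genes, and mitochondrial and heat shock genes as signs of RNA quality. The tests, lists, motif families, alternatives and naming rule were set before the data were examined, apart from those said to be chosen after.

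Named genes are Adamts7, then for each direction the 10 genes with the largest fold change among called genes whose libraries do not overlap between genotypes, filled up with the smallest unadjusted p, and from each list the 2 members with the smallest p and the 2 most abundant. Predicted gene models were counted and not named, with the exceptions stated, and some genes that the rule takes are not reported here. Named motifs are the 10 with the largest change in each direction and 6 families. Motif families were placed by the percentile of their median among 10000 random lists, which describes these pooled libraries and is no test. Random lists drew motifs regardless of the deposited motif clusters, whereas motifs of 1 family often share a cluster, so percentiles may overstate how far such a family stands apart. Bound shares carry 95% Wilson intervals. The correlation of footprint and RNA changes used 100000 permutations in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Gene positions came from a reference table of GRCm38.p6, in which 99.4% of the 36144 genes were matched; the position of Gm36961 is not given there.

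The tests were checked on simulated data. In 13131 simulated genes of this design, limma recovered 81 of 100 genes changed by a log2 fold of 1 and 97 of 100 changed by a log2 fold of 2, with 9 unchanged genes called. The change was equal in every simulated overexpression library, each gene had 1 SD for both genotypes, and the lowest genes were not changed. The real overexpression libraries differed more from each other than the wild-type ones, so recovery may be lower in the real data. Camera called the shifted list and 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this could not show false calls of lists whose genes move together. In the real data the estimated correlation of the macrophage list was 0.934. The motif comparison put a family shifted by 0.3 at percentile 100, and 0 of 20 unshifted families outside the middle 95%.

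Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of 5 TPM, median-of-ratios scaling, quantile normalisation, mitochondrial genes left out, the mouse number as a block, each library left out, other variance priors, quality weights, other thresholds and other list tests. For motifs they were at least 1000 sites, 1 motif per cluster, the difference of mean scores and a centred change. For the correlation they were a mean of 5 TPM, dimers left out and the difference of mean scores. A macrophage score (the mean log2 value of the macrophage list) as a covariate was added after seeing the data. No 2 libraries held identical values for any gene above 0, and pairwise correlations of log2 values were 0.961 to 0.991. The median SD of a gene between replicates was 0.0997 log2 units in wild type and 0.14 in overexpression cultures. The authors' column marking motifs was not used.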

Results

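The series compared primary smooth muscle cells grown from the aortas of wild-type male mice with cells from mice carrying a smooth muscle Cre driver (Myh11-Cre-ERT2) and Adamts7 overexpression. Adamts7 encodes a secreted metalloprotease that cleaves extracellular matrix proteins. The title of the series places the question in atherosclerosis, where smooth muscle cells that take up lipid become foam cells. RNA was measured in 3 libraries per genotype, each from its own mouse, and chromatin accessibility by ATAC-seq in 2 mice per genotype. The labels name no Cre driver for the wild-type mice, so the comparison holds the driver and the overexpression together. This form of Cre acts when tamoxifen is given, and which mice received it is not given in the sources used here, so tamoxifen may differ with genotype as well. Of the 36144 genes in the expression table, 18802 to 19184 were above 0 TPM in a library and 13021 to 13214 reached 1 TPM. Mitochondrially encoded genes took 12.0% to 14.3% of the TPM per library. TPM values keep no record of read number, so the sequencing depth behind them is unknown.

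Adamts7 RNA was 12.4 times as abundant in the overexpression cultures as in wild type. Its level was 6.82 ± 1.20 TPM in wild type and 84.5 ± 12.4 TPM in overexpression cultures (SD, n = 3 each). The wild-type libraries stood at 6.08, 6.18 and 8.20 TPM, and the overexpression libraries at 98.7, 79.1 and 75.8 TPM. The log2 fold change was 3.45 with a standard error of 0.14, and limma gave an adjusted p of 0.000357. A two-sided exact permutation test on the 6 libraries gave p = 0.1, the smallest value that 3 against 3 can reach. Adamts7 (ENSMUSG00000032363.15) lies on chromosome 9 from 90162904 to 90200102 in mm10 (GRCm38.p6), and the value covers the whole gene, with no separation of native and transgene transcripts. The titles of the overexpression RNA libraries begin with the wild-type abbreviation, whereas their genotype label names overexpression. All 3 of them lay above every wild-type library for Adamts7.

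**Figure D1:**
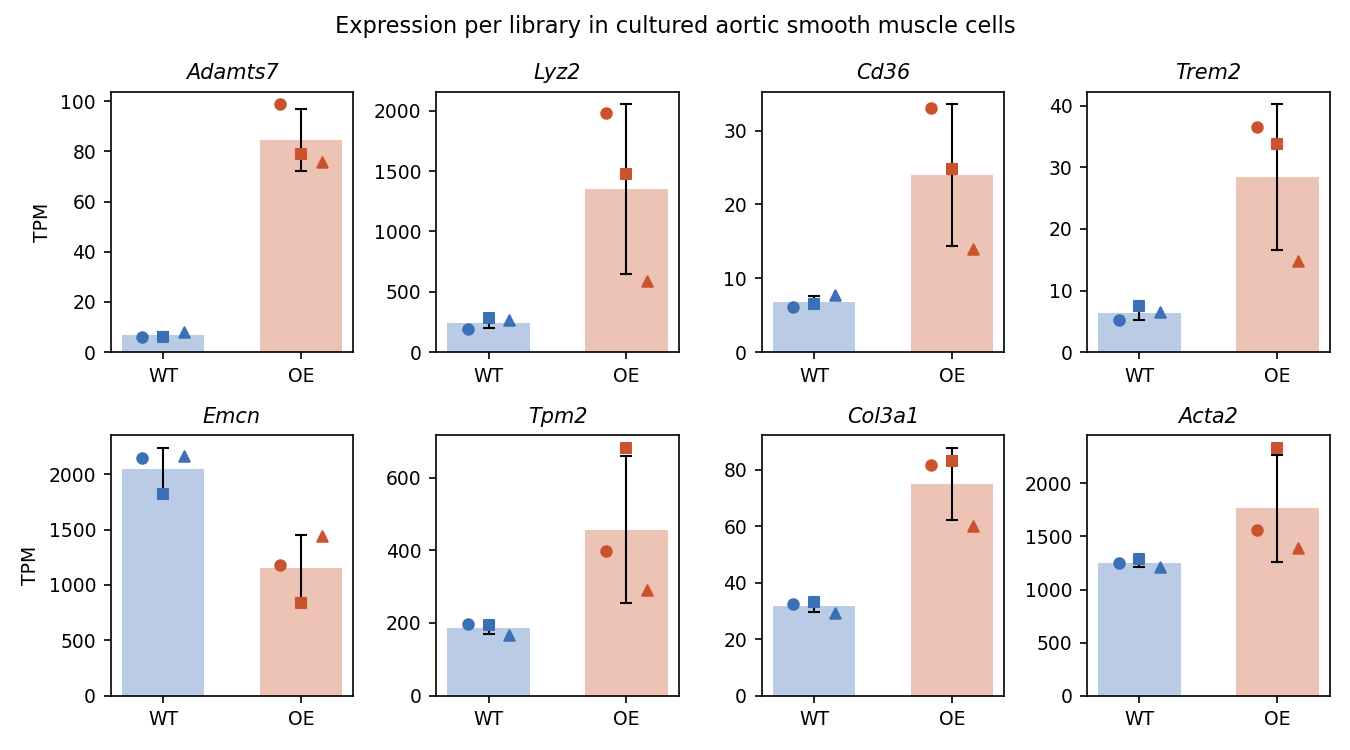
TPM of 8 genes in the 3 wild-type (WT) and 3 Adamts7 overexpression (OE) RNA libraries. Bars give the mean, error bars the SD, and points the single libraries, with circle, square and triangle for replicates 1, 2 and 3. Adamts7 is 6.82 TPM in wild type and 84.5 TPM in overexpression cultures, and for Lyz2, Cd36 and Trem2 overexpression replicate 3 is the closest of its group to wild type.

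Beyond Adamts7, single genes with the smallest p-values included collagen, actin-linked and myeloid genes on the higher side, but limma called only 2 of the 13131 genes tested. Both called genes were higher in overexpression cultures. The other was Gm36961 (ENSMUSG00000103930.1), a predicted gene model named here after its values were seen, which was listed at 0 in all 3 wild-type libraries and at 4.03, 3.92 and 4.12 TPM in the overexpression libraries (limma adjusted p = 0.00722). Its position is not given in the reference used here, and whether its reads come from the transgene or its vector was not tested. It was not called without wild-type replicate 2 (adjusted p = 0.0767) or with a macrophage score as a covariate, chosen after seeing the data (0.43), over alternatives ranging from 0.0023 to 0.43. AC087559.2, also named after its values were seen, was likewise listed at 0 in every wild-type library, stood at 2.87, 1.48 and 1.12 TPM in the overexpression libraries, and was too low to be tested. At an unadjusted p under 0.05 there were 2560 genes, 19.5% of those tested, 1386 higher and 1174 lower, where chance gives 657. The 3 libraries of one genotype lay wholly above those of the other for 27.2% of the genes, where chance gives 10%. Both chance values are averages, and counts can lie far from them where many genes move together. How far was not tested, as these 2 counts were not taken for other splits of the libraries.

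Among genes that did not pass, the smallest p-values on the higher side belonged to Col3a1, the chain of type III collagen, at 31.7 ± 2.21 TPM in wild type and 74.9 ± 12.8 TPM in overexpression cultures (SD, n = 3 each; adjusted p = 0.121). Next came Enah, an actin filament regulator, with a log2 fold change of 0.85, the stress gene Gadd45g with 0.76, the sarcomere protein gene Myom1 with 0.69 and the receptor tyrosine kinase gene Axl with 0.48. Serpinb9b had a log2 fold change of 0.91, and Pomp, which encodes a proteasome assembly factor, 0.53. The myeloid membrane protein genes Ms4a6d and Cd300c2 had 2.04 and 1.64. On the lower side stood Sppl2b, an intramembrane protease gene, with -0.89, Grip2 with -0.60 and the RNA-binding Lsm2 with -0.51. Slc8b1, a mitochondrial sodium-calcium exchanger gene, had -0.89, Gfpt2, of the hexosamine pathway, -0.70, and Fbrs, Mast4 and Ly6e -0.45, -0.39 and -0.36. The histone gene Hist2h2aa1 had -1.02, a value that is uncertain because its near-identical copy Hist2h2aa2 had 0.42. All of these genes other than Col3a1 had an adjusted p of 0.128. The count of called genes rested on single libraries: it was 828, with 524 higher and 304 lower, without overexpression replicate 3, 7 without overexpression replicate 1, 6 without overexpression replicate 2, 4 without wild-type replicate 1, 1 without wild-type replicate 2 and 4 without wild-type replicate 3. It was 2728, with 1491 higher and 1237 lower, when libraries were weighted by quality, and 1 when genes needed a mean of 5 TPM.

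Overexpression replicate 3 lay between the genotypes on the first principal component, which held 51.4% of the variance. Its score was -0.67, against -20.3, -16.8 and -20.2 for the wild-type libraries and 18.6 and 39.4 for overexpression replicates 1 and 2. Without it, 20 of 21 macrophage genes were higher, 8 of 16 endothelial genes were lower, and 11 of 28 matrix genes were higher and 1 lower past the threshold over all genes tested.

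Macrophage and leukocyte marker genes rose together in the overexpression cultures, with a median log2 fold change of 1.61 over 21 genes. Lyz2, the lysozyme of myeloid cells, stood at 246 ± 49.2 TPM in wild type and 1348 ± 704 TPM in overexpression cultures (SD, n = 3 each), a log2 fold change of 2.30 ± 0.41 (SE). Aif1, a macrophage calcium-binding protein gene, went from 6.04 to 22.7 TPM (log2 fold change 1.70 ± 0.29), and C1qa, a chain of complement C1q, from 74.8 to 287 TPM (1.79 ± 0.43). Adjusted over the list alone, 20 of 21 members rose; the exception, Cd74, named after its values were seen, had a log2 fold change of 0.11. The camera test with a preset correlation gave an adjusted p of 8.9e-15, with adjusted p = 0.343 with an estimated correlation. Per library, the list median relative to the wild-type mean was 2.18, 2.00 and 0.66 in overexpression replicates 1, 2 and 3, and between -0.25 and 0.22 in wild type. Endothelial genes were lower in the same libraries, with a median of -0.50.

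Genes of lipid uptake and foam cells rose as a group, with 9 of 22 members up adjusted over the list alone and a median log2 fold change of 0.39. Trem2, a lipid-sensing receptor of myeloid cells, stood at 6.40 ± 1.19 TPM in wild type and 28.3 ± 11.8 TPM in overexpression cultures, and Cd36, a scavenger receptor for oxidised lipoprotein, at 6.80 ± 0.82 and 24.0 ± 9.56 TPM (SD, n = 3 each). Their log2 fold changes were 1.90 ± 0.32 and 1.61 ± 0.28 (SE). Stab1, a scavenger receptor, was at 201 and 161 TPM and did not pass. Camera gave an adjusted p of 4.76e-07, with adjusted p = 0.343 with an estimated correlation. The macrophage list moved in the same libraries, with its median of 1.61, and the endothelial list with -0.50.

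**Figure D2:**
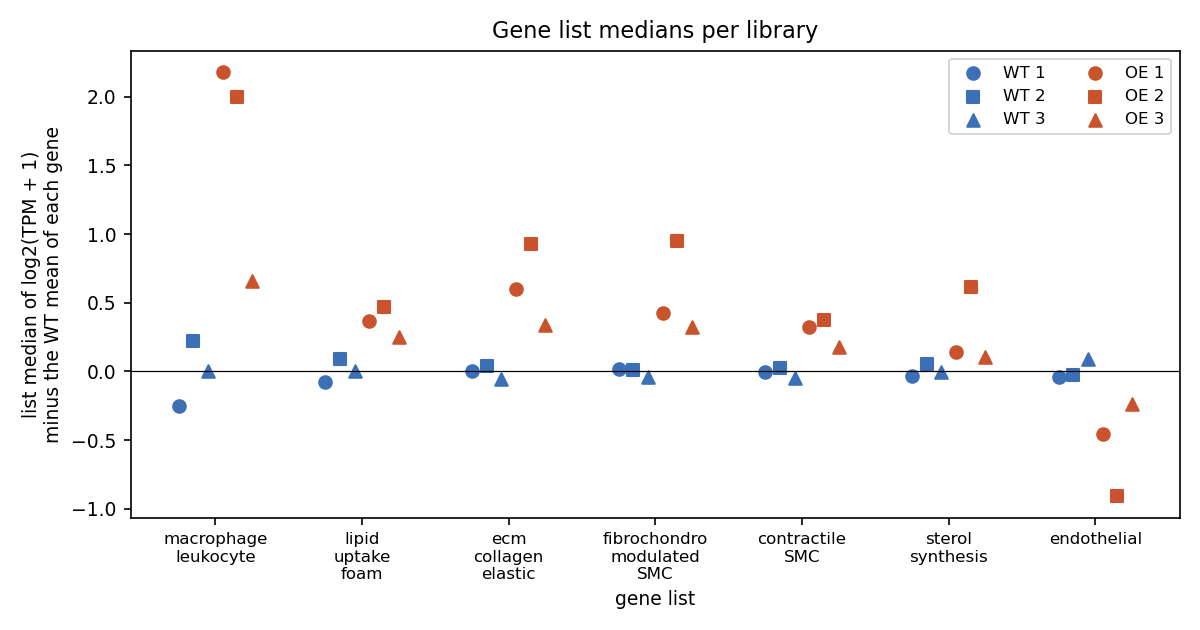
Median over the members of 7 gene lists of log2(TPM + 1) minus the wild-type mean of each gene, for each of the 6 RNA libraries (vertical axis, log2 units). Points stand for single libraries, blue for wild type and orange for overexpression. The macrophage median is 2.18, 2.00 and 0.66 in overexpression replicates 1, 2 and 3, and the endothelial median -0.45, -0.91 and -0.23.

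Contractile genes of differentiated smooth muscle also rose, with a median log2 fold change of 0.30 and 10 of 23 members up adjusted over the list alone. Tpm2, a muscle tropomyosin gene, was at 186 ± 17.1 TPM in wild type and 457 ± 202 TPM in overexpression cultures (SD, n = 3 each; log2 fold change 1.21 ± 0.28 SE). Mrvi1, which encodes a cGMP kinase substrate of smooth muscle, went from 4.65 to 12.0 TPM. Acta2, smooth muscle alpha-actin, was at 1249 ± 40.8 and 1764 ± 501 TPM, and Cald1, caldesmon, at 1554 and 1726 TPM, and neither passed. Camera gave an adjusted p of 9.43e-06, with adjusted p = 0.343 with an estimated correlation. Macrophage genes were higher and endothelial genes lower in the same libraries, with medians of 1.61 and -0.50.

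Extracellular matrix genes rose, with a median log2 fold change of 0.69 over 28 genes, and genes of modulated, chondrocyte-like smooth muscle rose with a median of 0.49 over 18. In the matrix list 13 members rose and 2 fell adjusted over the list alone, among them Col3a1, with 1.20, and the elastic fibre gene Fbln2, from 595 ± 45.1 to 935 ± 169 TPM (SD, n = 3 each), with 0.64. Sparc, an abundant matricellular protein gene, was at 2001 and 1947 TPM. In the chondrocyte-like list 6 of 18 members rose adjusted over the list alone. Col2a1, the cartilage collagen gene, was at 11.1 ± 0.57 TPM in wild type and 110 ± 87.8 TPM in overexpression cultures, and Sox9, the transcription factor of cartilage, at 6.47 ± 1.73 and 18.8 ± 7.29 TPM. ADAMTS, MMP and TIMP genes other than Adamts7 rose with a median of 0.27, and 7 of 19 passed adjusted over the list alone. Among them the aggrecanase gene Adamts5 had a log2 fold change of 0.89 and Mmp19 1.16, while the inhibitor gene Timp1 did not pass, with 0.27. Camera gave adjusted p-values of 5.65e-05 for the matrix list, 0.000199 for the chondrocyte-like list and 0.000978 for the protease list, each with adjusted p = 0.343 with an estimated correlation. Endothelial genes were lower by a median of -0.50 and macrophage genes higher by 1.61 in these libraries. Without overexpression replicate 2, which had the highest medians of the matrix and chondrocyte-like lists (0.93 and 0.95), the matrix median was 0.44 and the protease median 0.17, and camera still called both. With no filter on low genes the chondrocyte-like median was 0.24 and the protease median 0.099, and camera still called both of these lists.

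Enzymes of cholesterol synthesis rose as a group, with a median log2 fold change of 0.29 and 22 of 25 members higher. No member passed limma's threshold adjusted over the list alone, and 11 had an unadjusted p under 0.05, all higher. The mevalonate pathway gene Mvd was at 19.0 and 26.8 TPM (log2 fold change 0.46 ± 0.12 SE), and Msmo1, a sterol oxidase gene, at 150 and 187 TPM. Camera gave an adjusted p of 5.04e-06, with adjusted p = 0.538 with an estimated correlation. The median was 0.16 without overexpression replicate 2, and camera still called the list. Macrophage genes had a median of 1.61 and endothelial genes -0.50 in these libraries. Cholesterol efflux and lysosomal genes were not called, with a median of 0.080 and 0 of 17 members past limma's threshold adjusted over the list alone, against 5 at an unadjusted p under 0.05. The median was 0.027 without overexpression replicate 1, 0.040 and 0.049 without wild-type replicates 1 and 2, and 0.14 without overexpression replicate 2. In that list the efflux transporter gene Abcg1 had 0.79, the lysosomal acid lipase gene Lipa 0.53 and the apolipoprotein gene Apoe 0.42. Fatty acid synthesis genes were not called either, with a median of 0.11, 0 of 15 past limma's threshold adjusted over the list alone and 5 at an unadjusted p under 0.05. That median was 0.062 without wild-type replicate 3. Me1, which supplies NADPH, had 0.24 and the acyltransferase gene Gpam 0.38.

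Endothelial marker genes fell in the overexpression cultures, with a median log2 fold change of -0.50 and 12 of 16 members down adjusted over the list alone. Emcn, the endothelial sialomucin endomucin, was at 2046 ± 191 TPM in wild type and 1153 ± 302 TPM in overexpression cultures (SD, n = 3 each), a log2 fold change of -0.86 ± 0.19 (SE). Cdh5, the adhesion protein of endothelial junctions, was at 919 ± 48.1 and 612 ± 144 TPM, and the transcription factor gene Sox17 at 43.7 and 32.6 TPM. Macrophage genes were higher in the same libraries, with a median of 1.61. Camera gave an adjusted p of 4.82e-07, with adjusted p = 0.343 with an estimated correlation. By wild-type TPM among 36144 genes, Emcn was of rank 36 and Cdh5 of rank 129, but Vwf was of rank 7562 and Kdr of rank 9309. Of the smooth muscle genes, Acta2 was of rank 79 and Tagln of rank 142, but Myh11 was of rank 4459. Vwf, Kdr, Tagln and Myh11 were named outside the naming rule.

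Genes of the unfolded protein response rose by a small amount, with a median log2 fold change of 0.13, and proliferation and mitochondrially encoded genes fell, with medians of -0.11 and -0.12. The chaperone genes Hsp90b1 and Hspa5 had 0.23 and 0.27, the cyclin gene Ccnb2 -0.37, the replication helicase gene Mcm5 -0.25 and mt-Co1, a subunit of cytochrome c oxidase, -0.21. No member of the 3 lists passed limma's threshold adjusted over the list alone. At an unadjusted p under 0.05, 7 of 21 unfolded protein response genes were higher, 5 of 25 proliferation genes lower and 1 of 13 mitochondrial genes lower. Of all genes tested 19.5% had such a p, so the proliferation and mitochondrial counts did not stand out. Camera gave adjusted p-values of 0.00535, 0.003 and 0.0141, with adjusted p = 0.343, 0.538 and 0.538 with an estimated correlation. The mitochondrial call was lost without wild-type replicate 1 (median -0.061, adjusted p = 0.155), without overexpression replicate 3 (-0.090, adjusted p = 0.269), under quantile normalisation (-0.020, adjusted p = 0.598), under median-of-ratios scaling (-0.11, adjusted p = 0.089) and with no filter on low genes (adjusted p = 0.259), over alternatives ranging from 0.00109 to 0.598. The proliferation call was lost without wild-type replicate 3 (median -0.071, adjusted p = 0.0895, over alternatives ranging from 0.000535 to 0.538), its median was -0.063 without overexpression replicate 2 and -0.17 without overexpression replicate 3, and the unfolded protein response median was 0.076 without overexpression replicate 2. The macrophage and endothelial medians in these libraries were 1.61 and -0.50.

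The other tested lists were not called by camera. AP-1 genes had a median log2 fold change of -0.10, and 1 of 18, Atf3, rose adjusted over the list alone, with 0.55, while Maff had -0.29 and Nfe2l2 -0.23. NF-kB targets and cytokines had a median of -0.14, with Ccl2 at -0.57 and Cxcl12 at 0.23, and 0 of 16 passed limma's threshold adjusted over the list alone, against 3 at an unadjusted p under 0.05. That list was called lower without wild-type replicate 2 (median -0.23, adjusted p = 0.0396, over alternatives ranging from 0.0396 to 0.997). Its median was -0.24 without overexpression replicate 3, and nearer 0, at -0.044 and -0.084, without overexpression replicate 2 and wild-type replicate 3. Interferon-stimulated genes had a median of -0.019, with Oas1a at 0.39 and Ifi44 at -0.30, and 0 of 22 passed limma's threshold adjusted over the list alone, against 2 at an unadjusted p under 0.05. The unadjusted counts of the NF-kB and interferon lists were no larger a share than the 19.5% of all genes tested. Senescence and p53 genes had a median of -0.033, with Cdkn2a at 0.65, and 0 of 16 passed limma's threshold adjusted over the list alone, against 5 at an unadjusted p under 0.05. TGF-beta and YAP targets had a median of -0.016, a mean of 0.058 and a downward camera direction; 3 rose and 1 fell adjusted over the list alone, with Axl at 0.48 and the integrin gene Itgb5 at 0.61 among those that rose, while Ccn2 had 0.18. Hypoxia and glycolysis genes had a median of -0.0018, which was 0.0089 under median-of-ratios scaling, a mean of -0.042 and an upward camera direction, and 2 of 22, Adm and Vegfa, fell adjusted over the list alone, with -0.63 and -0.42. Heat shock and immediate early genes had a median of 0.082, and 1 of 16, Hspa1b, rose adjusted over the list alone, with 0.56, while Nr4a1 had -0.43. Adventitial fibroblast markers had a median of 0.11, and 2 of 11 rose adjusted over the list alone, among them Gsn, with 0.31, while Cd34 had -0.46 at 1001 TPM in wild type.

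Lists with fewer than 5 tested members were described and not tested. Striated muscle genes had a median of 0.56 over 4 genes, with Tnnt2 at 1.16, Schwann cell genes 0.33 over 4, Y-linked genes 0.12 over 4, globin genes -0.37 over 2, and epithelial genes -0.46 over 3, with the keratin genes Krt19 at 0.74 and Krt18 at -0.52, the latter -0.30 without overexpression replicate 2. These medians rest on few genes and on single libraries: the Schwann cell median was 0.50 without overexpression replicate 3 and 0.20 without wild-type replicate 2, the striated muscle median 0.33 without overexpression replicate 2, and the epithelial median -0.29 without overexpression replicate 2 and 0.077, over 2 genes, without wild-type replicate 1. With no filter on low genes the medians were 0.19 for Schwann cell, 0.13 for striated muscle, -0.14 for globin and 0.021 for epithelial genes. No adipocyte marker reached a mean of 1 TPM. Over the 27 lists, 21 were tested, and camera called 8 higher and 3 lower. With an estimated correlation camera called 0, with 1 list at an unadjusted p under 0.05, and fry called 0, with 9 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.0931. No member of any list passed limma's threshold over all genes tested, while 167 of the 410 genes in the lists had an unadjusted p under 0.05, 122 higher and 45 lower. With the macrophage score of each library as a covariate, an alternative chosen after seeing the data, 2 lists were called, the mitochondrial list and the interferon list, both lower.

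**Figure D3:**
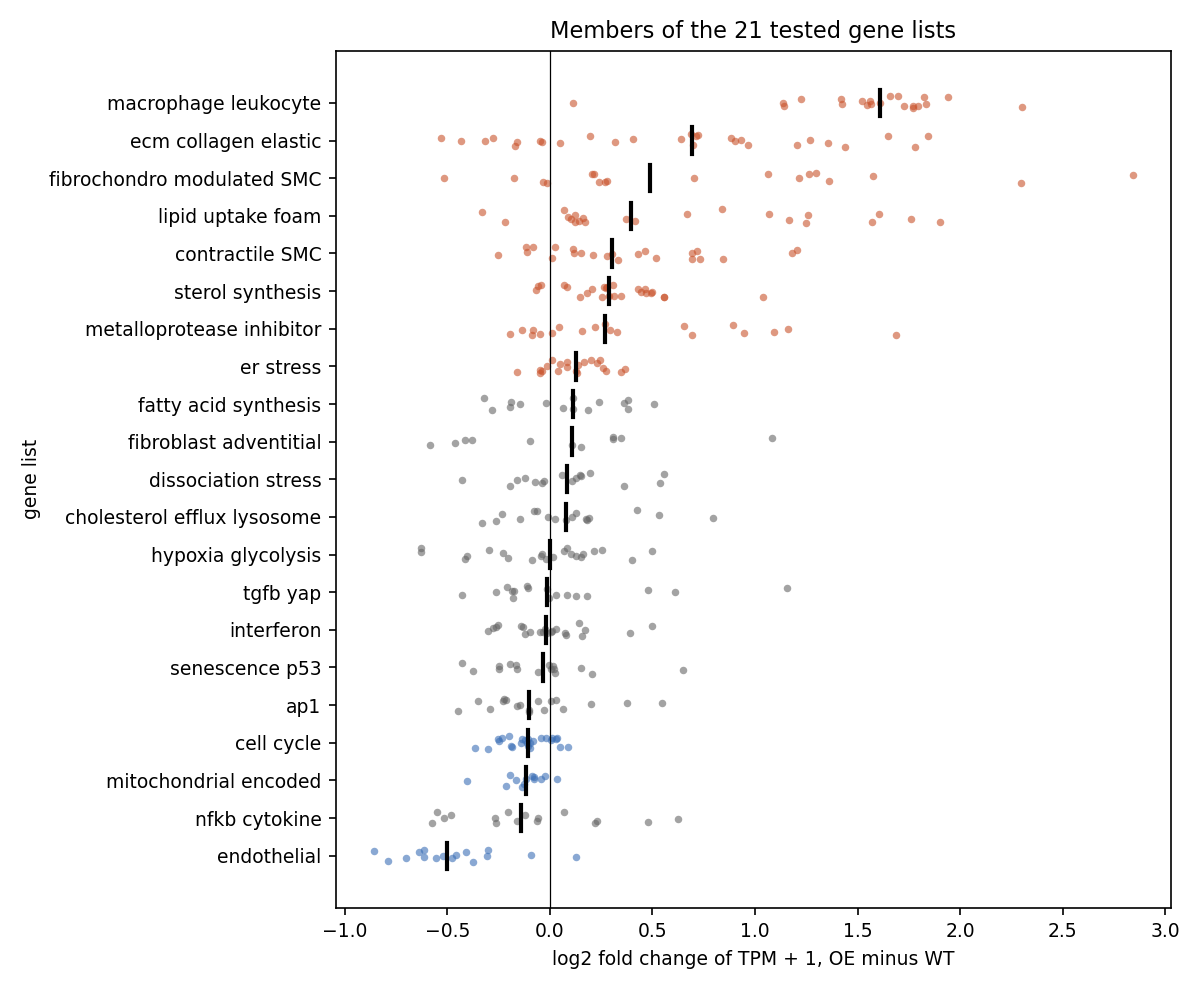
log2 fold changes of TPM + 1 (overexpression minus wild type, horizontal axis) of the members of 21 gene lists, 1 point per gene, with the list median as a black bar. Orange lists were called higher and blue lists lower by camera with a preset correlation, and grey lists were not called. Medians run from 1.61 for macrophage genes to -0.50 for endothelial genes.

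The ATAC-seq comparison asked which transcription factor motifs had stronger or weaker footprints, that is, protection from transposase cutting at motif sites, when Adamts7 was overexpressed. The deposited scores come without a separate measure of how open the sites were. A change in protection therefore cannot be told apart from a change in openness. In the authors' deposited table, AP-1 motifs, bound by FOS and JUN dimers, and MEF2 motifs had higher footprint scores in overexpression cultures, while motifs of SNAI and ZEB1, repressors that bind E-boxes, had lower scores. The authors' deposited table gives 1 pooled value per genotype for each motif, so these differences have no replicate check. Of the 879 motifs, the authors' deposited table had 544 higher and 335 lower in overexpression cultures, 61.9% higher, and 439 higher and 439 lower once the change was centred on the median motif. The median change was 0.11 in the authors' deposited table, which gave a p not under 0.05 for 3 motifs. Each motif had 903 to 212951 sites in the authors' deposited table, with a median of 18670.

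Of the 10 motifs with the largest change toward overexpression in the authors' deposited table, 8 were AP-1 dimers, between 0.64 for FOS::JUN and 0.66 for FOSL1::JUNB, and the others were ZNF384 with 0.68 and Hmga1 with 0.66. In the authors' deposited table FOSL1::JUNB had a mean score of 0.240 in wild type and 0.307 in overexpression cultures, and bound sites were 13.5% (95% Wilson interval 13.1 to 13.8) and 19.0% (18.6 to 19.4) of 38169. Over the AP-1 and MAF family, 49 of 51 motifs were higher in the authors' deposited table, with a median change of 0.33 that lay at percentile 100 of 10000 random motif lists matched on mean score. The 51 motifs belong to only 7 clusters, so they are not independent of each other. The median bound share of that family was 14.4% in wild type and 18.3% in overexpression cultures in the authors' deposited table. In the RNA libraries the 19 genes of that family's factors had a median log2 fold change of -0.056, 8 higher and 11 lower, and limma called 0 of them.

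Motifs of MEF2 and SRF, activators of muscle genes, had a median change of 0.59 in the authors' deposited table, with 5 of 5 higher and a percentile of 100. That median is a MEF2 value, as the 4 MEF2 motifs, all of 1 cluster, lay between 0.58 and 0.63 and the SRF motif was at 0.17 in the authors' deposited table, and it was 0.38 with 1 motif per cluster. TEAD motifs, bound by the partners of YAP, had a median change of 0.39 in the authors' deposited table, with 4 of 4 higher, all of 1 cluster, and a percentile of 100. RUNX motifs had 0.12 and SPI motifs, bound by the myeloid factor PU.1, also 0.12 in the authors' deposited table, at percentiles 80.6 and 70.2, and 0.017 and 0.014 after centring on the median motif, while SPI had 0.19 with 1 motif per cluster. KLF, SP and EGR motifs had a median change of -0.017 in the authors' deposited table, at percentile 48.9, -0.12 after centring and -0.063 with 1 motif per cluster, while the bound share was lower with separate Wilson intervals for 26 of 27. In the RNA libraries limma called 0 factor genes of these 5 families; the medians were -0.027 over 4 SRF and MEF2 genes, 0.016 over 4 TEAD genes, 0.62 over 3 RUNX genes, 1.13 over 2 SPI genes and -0.0030 over 22 KLF, SP and EGR genes.

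The 10 motifs with the largest change toward wild type in the authors' deposited table were SNAI2 with -0.44, SNAI3 with -0.42, TCF4, ZEB1, FIGLA, SNAI1 and TCF3 each with -0.39, Ptf1A with -0.37, ZBTB14 with -0.33 and MSANTD3 with -0.32. ZEB1 and FIGLA held identical values in the authors' deposited table, as did SNAI1 and TCF3. For SNAI2 the bound share in the authors' deposited table was 5.50% (95% Wilson interval 5.20 to 5.81) of 21902 sites in wild type and 4.15% (3.89 to 4.42) in overexpression cultures. The 4 ZEB1 and SNAI motifs, a planned family picked for naming after its values were seen, had a median change of -0.41 in the authors' deposited table, at percentile 0 of the random lists. They belong to 2 clusters, and the median was -0.39 with 1 motif per cluster.

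**Figure D4:**
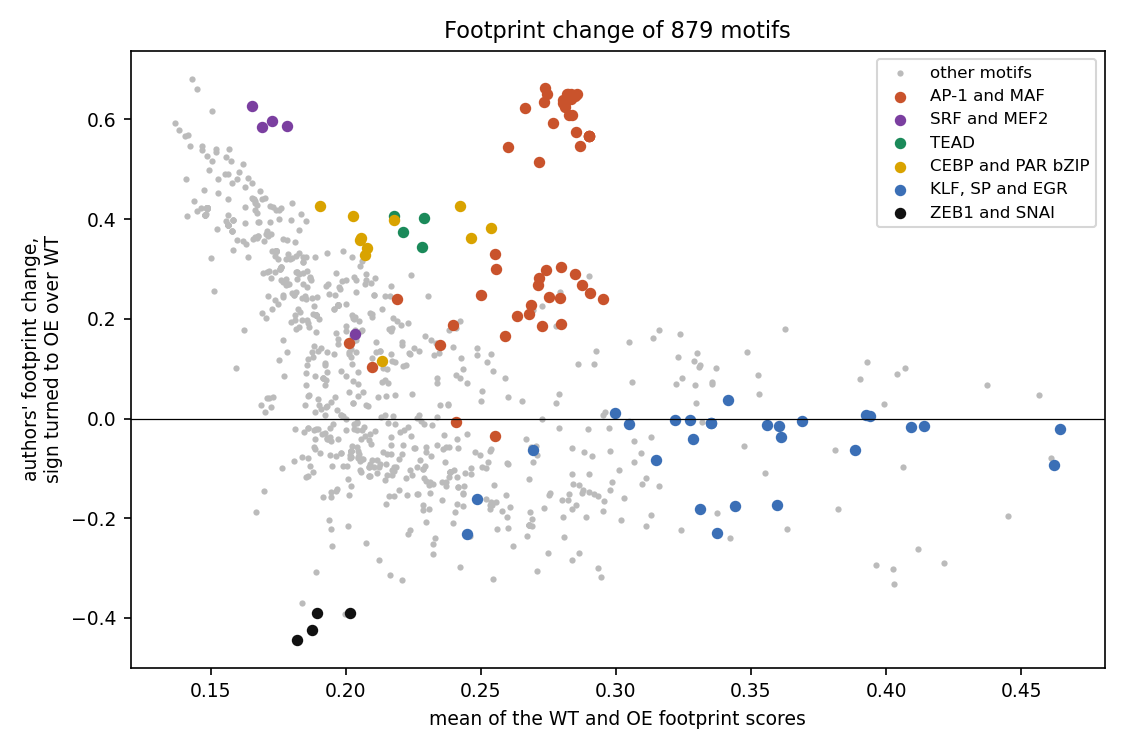
Change of the footprint score of 879 motifs from the authors' deposited table, with the sign turned so that positive values are higher in overexpression cultures (vertical axis), against the mean of the wild-type and overexpression scores (horizontal axis). Each point is 1 motif; the coloured families are AP-1 and MAF, SRF and MEF2, TEAD, CEBP, KLF with SP and EGR, and ZEB1 with SNAI. AP-1 motifs lie up to 0.66 and SNAI2 at -0.44.

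Bound shares moved in the same direction as footprint scores for 778 of the 879 motifs in the authors' deposited table. The bound share was higher in overexpression cultures for 552 motifs (62.8%), lower for 326 and equal for 1 in the authors' deposited table. Wilson intervals, which cover counting error only, were separate and higher for 270 motifs and separate and lower for 172. The median bound share was 8.14% in wild type and 8.49% in overexpression cultures in the authors' deposited table.

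Across 375 factors with both values, the footprint change in the authors' deposited table had a Pearson r of -0.038 with the log2 fold change of the factor's gene (permutation p = 0.466, adjusted 0.466). Spearman's rho was -0.095 (permutation p = 0.0661, adjusted 0.132 over these 2 coefficients). Factors are genes, not independent replicates, and many share a motif.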

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

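Adamts7 stayed past the threshold in every setting run for it (other variance priors and quality weights were run for the gene count only), with log2 fold changes between 3.17 and 3.62, 3.34 to 3.58 when single libraries were left out, and adjusted p-values up to 0.0384. The median of all genes shifted by less than 0.1 in every setting. The count of 2 called genes was 1 when a mean of 5 TPM was required, which left out Gm36961, and 2728 with quality weights, which gave overexpression replicate 1 a weight of 5.66 and replicates 2 and 3 weights of 0.28 and 0.49; it ranged from 1 to 828 when single libraries were left out. The cause was not tested. The mouse numbers did not pair the libraries (correlations of deviations -0.022, 0.058 and 0.018 for equal numbers), and with the mouse number as a replicate block the count was 1, as Gm36961 had an adjusted p of 0.0907, and the list count 11, with no other call changed. Gm36961 was also not called without wild-type replicate 2 and with the macrophage covariate (adjusted p = 0.0767 and 0.43, over alternatives from 0.0023 to 0.43). Of 71 named genes besides Adamts7, 25 kept direction and side of the threshold in all 14 settings set beforehand, and 44 that did not pass with all libraries did so without overexpression replicate 3. Without overexpression replicate 2 log2 fold changes came nearer 0 for Acta2 (0.24), Ccn2 (0.035), Cd34 (-0.26), Msmo1 (0.17), Nfe2l2 (-0.11) and Stab1 (-0.18), without wild-type replicate 1 for Apoe (0.25), and with quantile normalisation for Cald1 (0.027), Ccn2 (0.066) and mt-Co1 (-0.064), while Sparc ranged from -0.089 to -0.010 when single libraries were left out and was at -0.17 with quantile normalisation.

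The count of 11 called lists was 0 with an estimated correlation, 0 with fry and 2 with the macrophage covariate (chosen after seeing the data), and 10 to 12 when single libraries were left out. That covariate is made from the macrophage list, so by construction it takes away that list's change. With it, medians turned for the macrophage list (-0.029) and the fatty acid (-0.0012), NF-kB (0.040), proliferation (0.018) and TGF-beta lists (0.059), and log2 fold changes for C1qa (-0.029), Cd34 (0.079), Cdkn2a (-0.063) and Cd74 (-0.97); contractile (0.12), lipid uptake (0.17), matrix (0.16), chondrocyte-like (0.12), protease (0.11), sterol (0.093), unfolded protein response (0.076) and endothelial genes (-0.16) kept their sign and were not called, and the interferon list was called lower (-0.26, adjusted p = 0.000103, over alternatives from 0.000103 to 0.997). Medians near 0 also turned: fibroblast markers with a mean of 5 TPM (-0.037), interferon genes with no filter (0.0070), and hypoxia genes with a mean of 5 TPM (0.014) and median-of-ratios scaling (0.0089). When single libraries were left out, ranges crossing 0 were -0.0136 to 0.22 for fibroblast markers, -0.062 to 0.044 for interferon genes, -0.019 to 0.031 for hypoxia genes, -0.0056 to 0.15 for heat shock genes and -0.33 to 0.39 for Cd74; senescence genes ranged from -0.069 to -0.026 and TGF-beta and YAP targets from -0.10 to -0.0050. The cause was not tested. Of 21 lists, 5 kept direction and side in all 17 settings set beforehand. Leaving out mitochondrial genes removed the mitochondrial list and mt-Co1, and 4 named genes did not reach a mean of 5 TPM, so these had no value there.

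The share of motifs higher in overexpression in the authors' deposited table was 61.9% (Wilson interval 58.6 to 65.0), 55.9% with 1 motif per cluster, 56.4% from the difference of mean scores and 49.9% after centring, which sets it near this value by construction. That interval takes the 879 motifs as independent, although they fall in 406 clusters. With at least 1000 sites the share of motifs higher was 61.9%, and the share of motifs with a higher bound share 62.8%. The correlation with RNA kept its sign and side in 3 alternatives. TPM without read number leave the counting error of low genes unknown.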

Other observations

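The marker lists and the tests of explanations in this part were chosen after the results were seen, except that the other scalings and the score-matched motif lists they draw on were planned. Further lists described the myeloid and vascular genes in more detail. Of 12 resident macrophage genes, 6 were tested and had a median log2 fold change of 0.93 (camera adjusted p = 0.00348, and p = 0.117 with an estimated correlation), from 1.63 for Pf4 and 1.52 for Mrc1 to 0.037 for Gas6 (limma unadjusted p = 0.704). Not every listed gene was higher: Lyve1, too low to be tested, was at 0.77, 1.27 and 0.74 TPM in wild type and 0.35, 0.66 and 0.65 TPM in overexpression cultures, Timd4 and Cd209f were at or near 0, and with no filter the median was 0.47 over 11 genes. Folr2, at 0.55 TPM in wild type and 2.14 TPM in overexpression cultures, was left out of the test without overexpression replicate 2. Antigen presentation genes had a median of 0.092 over 6 genes, lysosomal genes 0.045 over 13, arterial endothelial genes -0.23 over 10, sinusoidal and lymphatic endothelial genes -0.33 over 5, pericyte genes 0.36 over 6 and monocyte genes 0.62 over 2, and camera, run on these lists with all libraries only, called none of these 6. Single libraries set several of these medians: antigen presentation genes were at -0.24 without overexpression replicate 1, 0.28 and 0.31 without overexpression replicates 2 and 3, 0.030 without wild-type replicate 1 and 0.17 without wild-type replicate 2, and lysosomal genes between -0.0055 and 0.095. Without overexpression replicate 2 arterial endothelial genes were at -0.12 and sinusoidal and lymphatic endothelial genes at -0.18, and without overexpression replicate 1 monocyte genes at 0.40. With no filter sinusoidal and lymphatic endothelial genes had -0.11, pericyte genes 0.059 and monocyte genes 0.0078. Lymphocyte and neutrophil or mast cell genes each had 1 member above the expression filter, at -0.50 and -0.099, the latter between -0.32 and 0.075 when single libraries were left out.

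Among the planned motif families, others, picked for naming after their values were seen, lay outside the middle 95% of score-matched random lists in the authors' deposited table. CEBP motifs had a median change of 0.36 with 11 of 11 higher, ETS motifs other than SPI 0.14 with 46 of 53 higher, both at percentile 100, and IRF motifs 0.30 at percentile 99.99 in the authors' deposited table. STAT motifs, with 0.27 at percentile 98.1, and HOX motifs, with 0.40 at percentile 98.8 in the authors' deposited table, lay just above the upper ends of 0.269 and 0.394. Score-matched lists of HOX size had a median of 0.353, so most of the HOX value was usual for motifs of low score. Lower were MYC, USF and MITF motifs with -0.15 and 31 of 37 lower, and TBX motifs with -0.12 and 13 of 14 lower, both at percentile 0 in the authors' deposited table. TCF21, TWIST and related motifs had -0.12 with 18 of 20 lower, at percentile 0.02 in the authors' deposited table. Of them 13 had separate lower Wilson intervals. PPAR, RXR, LXR and related motifs had -0.065 with 27 of 33 lower, at percentile 0.18, though 0 had separate Wilson intervals. ZNF motifs had -0.054 with 47 of 77 lower, at percentile 1.13. CREB and ATF motifs had 0.11 with 8 of 14 higher, at percentile 98.5 in the authors' deposited table. After centring on the median motif the ETS value was 0.028, IRF 0.19, STAT 0.17, MYC, USF and MITF -0.26 and TBX -0.22. In the authors' deposited table the median bound share of ETS motifs was 12.3% in wild type and 12.2% in overexpression cultures, and that of TBX motifs 6.09% and 6.24%, with 0 of 14 TBX motifs having separate Wilson intervals. POU motifs had 0.34 at percentile 20.8 in the authors' deposited table, also a usual change for such motifs.

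Of the 10 splits of the 6 RNA libraries into 3 and 3, 1 gave as many called genes as the real one, the real one itself, with 2 genes against a highest of 0 in the others. For the count of called lists, 4 of the 10 splits gave as many, with 11 in the real split and 11 as the highest of the others. The count of called lists therefore did not set the real split apart from the others. With 10 splits a share under 0.05 is not possible for either count.

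Macrophage genes were higher by a median log2 fold of 1.61, and Lyz2, C1qa and the rest of the 21 were also present in wild type, at a median of 12.9 TPM; no sort was used, the adventitia was removed before culture, and library scaling was argued against, since the lowest median under 3 other scalings was 1.597 against 1.611. A candidate explanation is more macrophages in the overexpression cultures: over the 20 markers with a log2 fold change of at least 1, the log2 ratio of the excess in overexpression replicate 1 to that in replicate 2 had an SD of 0.258, against 1.11 over 17 matrix, chondrocyte-like and contractile genes chosen by the same fold. Those 17 genes pool 3 lists, whereas any single set of genes that move together would have a small SD. The contrast therefore cannot decide for added macrophages. The marker left out by that fold, Cd74, goes against 1 fixed macrophage RNA profile, with 170 TPM in overexpression replicate 1 but 72.2 and 62.1 TPM in replicates 2 and 3, and the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 were also above every wild-type library in replicate 1 alone, with H2-Aa at 31.5, 12.7 and 14.8 TPM. Lipid uptake genes had a median ratio of 0.27 over 8 genes (SD 0.65), near the macrophage median of 0.24 and far from the -1.28 of the 17 genes, so part of the lipid uptake change may share a source with the macrophage genes. Smooth muscle cells in a macrophage-like state cannot be told apart from added macrophages with 3 overexpression libraries, although the macrophage excess in replicate 2 over replicate 3 was 2.48 log2 units where that of Adamts7 was 0.068.

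Endothelial genes were abundant in all 6 libraries and lower in overexpression cultures, by a median of -0.50. Endothelial cells in the cultures are a candidate explanation for their presence, as 12 of 16 endothelial markers reached 10 TPM in all 6 libraries against 4 of 40 markers of adipocytes, Schwann cells, epithelium and striated muscle; Emcn stood at 2046 TPM in wild type, but Vwf and Kdr at only 16.4 and 8.96 TPM. A lower endothelial share that raises every other cell type alike was argued against, because macrophage and contractile medians differed by 1.31, with a combined SD of 0.588. Dilution of all other types alike by added macrophages was argued against too, because contractile and endothelial medians differed by 0.804, with a combined SD of 0.477. Both comparisons cover only shifts that are alike over the other cell types. An uneven change in the shares of several cell types stays open and was not tested. An effect of Adamts7, of the Cre driver, of tamoxifen or of passage on endothelial genes or cells stays open and was not tested. The passage of each library is unknown, so its part in the macrophage change was not tested either.

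AP-1 footprints were higher in overexpression cultures in the authors' deposited table. For the fall of the change with baseline score, the AP-1 median of 0.3305 lay above the upper end, 0.1648, of the middle 95% of score-matched lists. Those lists ignored clusters, whereas the 51 AP-1 motifs belong to 7 clusters. The comparison is therefore a description and cannot decide whether the baseline score is the whole cause. A general rise of AP-1 mRNA was not seen, with a median log2 fold change of -0.056 and an SD of 0.329 over 19 genes. Of these, 8 were higher and 11 lower, and limma called 0. A rise of single AP-1 genes stays open, and AP-1 activity might also change without its mRNA. Chromatin of added macrophages also cannot be told apart, as SPI motifs had 0.1207, within random lists that reach 0.2765. The pooled scores keep no replicate and no separate measure of openness, so neither an effect of 1 mouse nor a change in openness was tested.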
